A study of Arabidopsis thaliana with 15 samples.

How the data were processed

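The series measured gene expression in whole seedlings of Arabidopsis thaliana accession Col-0 on 1-colour Agilent oligonucleotide arrays. Seedlings grew for 2 weeks on plates with 16 h of light and 8 h of darkness. Cold-treated seedlings then spent 7 days at 2 °C with 12 h of light and 12 h of darkness, and deacclimated seedlings were returned from the cold to the growth temperature. There were 5 groups of 3 arrays, which the series text describes as independent biological samples: untreated, 7 days of cold, and 4, 10 or 24 h after the return. The sample titles and the treatment protocol give 4, 10 and 24 h, while the design text of the series gives 6, 12 and 24 h. The hours of the titles are used here as group names. The labels do not give the hour of the day at which seedlings were taken.

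The deposited scanner files hold, per the file headers, the processed signal intensity of each spot, with background subtracted and spatial trends removed within the array by Agilent Feature Extraction 9.1.3.1. No scaling between arrays had been applied to these intensities. They also hold raw mean and local background intensities and, as other columns, spot flags. The authors' value table holds a linear intensity, which is the processed signal divided by 1 constant per array and floored at 0.01. Between 37.7% and 40.4% of each of its columns lay at that floor. Of its 15 columns, 13 matched their own scanner file, and those of replicates 1 and 2 at 4 h matched each other's file. The scanner files were the source of the values, and the value table served as an alternative.

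Each array held 37685 non-control spots for 37478 probes, of which 26236 carried a locus. Between 61.7% and 66.9% of spots were well above background by the scanner's flag, and no spot was saturated or had a signal of 0 or less. The log2 processed signal had the 75th percentile of its array subtracted. A spot marked as a non-uniformity outlier was left out where another spot of its probe remained. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which left 24254 probes. A gene was represented by its tested probe with the highest mean signal, which gave 21100 genes. The 2662 tested probes without a locus were counted apart. Symbols came from the reference gene table or, for listed genes, from the lists.

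All 15 arrays entered 1 fit with a mean per group in limma 3.58.1 under R 4.3.3, with moderated statistics and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05 and an at least 2-fold difference. The 7 planned comparisons were cold with untreated, each deacclimation time with cold, 24 h with untreated, and each deacclimation time with the one before. Comparisons of 4 h and 10 h with untreated and of 24 h with 4 h were added after seeing the data. Errors of log2 fold changes are standard errors from the fit with 3 arrays per group. They measure the spread between arrays, and the number of arrays limits the precision. The share of the cold change left was the median over cold-called genes of the difference from untreated divided by the cold difference. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists of a comparison, with camera at an estimated correlation and fry beside it. Fry asks whether a list's genes move one way on balance and does not compare them with other genes.

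The lists and the rule for naming genes were fixed before the data were examined, and so were the tests and alternatives other than those named as chosen after seeing the data. The lists were cold effector genes, cold transcription factors, circadian clock, heat shock, photosynthesis, flavonoid and anthocyanin, starch and sugar, proline, cell wall loosening, auxin response, gibberellin, abscisic acid and dehydration, jasmonate, salicylate defence, cell cycle, cytosolic ribosomal proteins, light stress and reactive oxygen, dark and sugar starvation, touch and wounding, flowering time, lipid desaturation, root markers and reference genes. Of their 422 genes, 419 were measured. In cold against untreated and each time against cold, the text names the 5 largest rises and 5 largest falls among called genes with a symbol, no overlap between groups and signal above background in both. It also names up to 3 called members of a list whose test passed or that had at least 3 called members, with up to 1 member against the list's majority. CBF1, CBF2, CBF3, COR15A, RD29A, CCA1, LHY, TOC1, PRODH1 and FLC belong to the rule whether called or not. In the other comparisons the rule takes the 3 largest rises and falls. A gene below background on all arrays of 1 group has a lower bound in place of a fold.

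Array position and scan day were read from the scanner files. Each untreated array lay alone on a slide of its own, and the other 12 arrays lay on 4 slides. Slides 2 and 6 held 1 array each of cold, 4 h, 10 h and 24 h, slide 4 held 1 each of cold, 10 h and 24 h, and slide 7 held replicate 2 at 4 h alone, which was also the only array of its scan day. Among the cold and deacclimated arrays, replicates 1, 2 and 3 lay on slides 2, 4 and 6, apart from replicate 2 at 4 h, so a replicate number also marks a slide there. Same-numbered arrays deviated together at above 0.1 for every number in 1 of 10 group pairs, 4 h and 24 h (0.361, 0.147 and 0.185; with numbers 1 and 2 at 4 h exchanged, as in the value table, -0.213, -0.0807 and 0.185), and the correlations ran from -0.141 to 0.382 over the pairs. The planned fit has no block, and fits with slide, scan day or replicate number as a block stand beside it. Untreated, cold, 10 h and 24 h had equal numbers of arrays on each scan day, and cold, 10 h and 24 h lay on the same slides. Each group held 1 array of each replicate number. A slide or scan day block therefore cannot alter fold changes among these groups, nor a replicate block any fold change. Such blocks alter only the estimated spread, so similar counts there are no check on a batch. Replicate 2 at 4 h was the only array of its slide and scan day. A fixed block by slide or scan day takes it out of the comparisons with 4 h, which then rest on replicates 1 and 3. Calls were tested on simulated data in which 200 of 21100 genes had been changed. With the 2-fold threshold, no gene changed by 0.5 on the log2 scale was recovered, while 86.3% of those changed by 1.5 and 95.5% of those changed by 2.5 were recovered, with 1 false call. The lack of recovery at 0.5 largely follows from the threshold. The simulated noise was independent between genes, and the scaling was not repeated. In the real cold comparison 26.9% of genes were called, so these rates may not hold there.

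Alternatives covered background correction by normexp with an offset of 50, median and quantile scaling, filters on dim probes, the probes of a gene, the variance model, array weights, fold thresholds, the arrays in the fit, replicate, slide and scan day as blocks, the authors' value table, and leaving out each array. The blocks by scan day, the exchange of replicates 1 and 2 at 4 h, the genes called without a slide or scan day, the list tests at 4 h under a block with an estimated correlation, the comparison of cold and 24 h with different untreated arrays, and the added comparisons were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Control spots were left out. Freezing tolerance, proteins and metabolites were not analysed here.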

Results

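The data comprised 15 arrays of whole Arabidopsis seedlings, with 3 arrays in each of 5 groups. The groups were untreated seedlings, seedlings after 7 days at 2 °C, and cold-treated seedlings 4, 10 and 24 h after their return to the growth temperature. The 75th percentile of the processed signal lay between 2148 and 3127 over the arrays, and 21100 genes were tested. Within groups, arrays correlated across genes at 0.986 to 0.996, and genes are not independent replicates. The rms log2 difference between group means was 1.18 for cold and untreated and 0.50 for 24 h and untreated.

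After 7 days of cold, 5666 genes, 26.9% of those tested, differed from untreated seedlings, with 2641 higher and 3025 lower. This comparison addresses cold acclimation, but the cold-treated seedlings also had 12 h of light a day in the cold, against 16 h for untreated seedlings. The 7 days in the cold may have left them older at sampling, and the hour of the day at sampling may differ too. Temperature cannot be told apart from light period, age and hour in the gene counts and lists of this comparison. COR27 (AT5G42900), a cold-induced regulator tied to the clock, rose most, 384-fold with a log2 fold change of 8.59 ± 0.19 (SE, n = 3 arrays per group; adjusted p = 1.5e-11). COR15B (AT2G42530), which encodes a chloroplast protein protective in freezing, was 132-fold higher, at 7.04 ± 0.33 on the log2 scale. The early light-induced protein genes ELIP1 (AT3G22840) and ELIP2 (AT4G14690) rose 102-fold and 70.6-fold, and the anthocyanin glycosyltransferase gene UGT79B1 (AT5G54060) rose 68.7-fold. The largest fall was that of GASA6 (AT1G74670), a gibberellin-responsive peptide gene, which was 423-fold lower with a log2 fold change of -8.73 ± 0.36 (adjusted p = 1.7e-09). The xylosidase gene BXL1, the growth-related SAUR19, the antenna gene LHCB2.3 and DR4 were 129-fold, 104-fold, 97.0-fold and 93.6-fold lower.

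**Figure D1:**
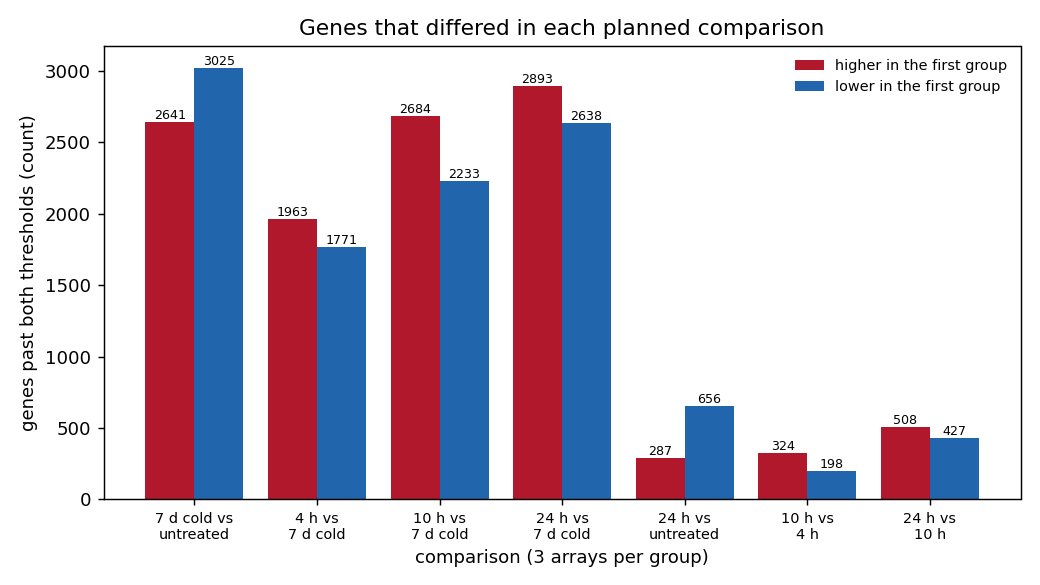
Bars give the number of genes (vertical axis, count) higher (red) and lower (blue) in the first group of each planned comparison (horizontal axis), with 3 arrays per group. Cold against untreated gave 2641 and 3025 genes, and 24 h against untreated gave 287 and 656.

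Among the cold effector genes, 16 of 20 measured members rose, 1 fell and 3 did not pass, with the same counts when adjusted over the list alone. COR15A and RD29A, markers of acclimation, were 44.8-fold and 44.3-fold higher, and GOLS3, a galactinol synthase gene, was 49.0-fold higher. RCI2B, a small membrane protein gene, fell by 2.08 ± 0.26 on the log2 scale. The list's camera adjusted p was 3.7e-06, with an adjusted p = 0.146 with an estimated correlation. Among the upstream activators, log2 fold changes after 7 days were -1.67 ± 1.29 for CBF1 and 0.83 ± 1.13 for CBF2, neither called, and 1.103 ± 0.412 for CBF3, a call that ended when replicate 1 or 2 of cold or replicate 2 or 3 of untreated was left out (0.90 to 1.13). The CBF genes are near-identical tandem copies, so a probe can carry signal from more than 1 copy. Of 21 cold transcription factors, 4 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.552). RAP2.1 was 3.81-fold and CZF1 2.51-fold higher.

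Flavonoid and anthocyanin genes rose together, with 20 of 22 higher and none lower, also when adjusted over the list alone. PAP2, an activator of the pathway, was called higher, with signal above background on 1 of the 3 untreated arrays, so no fold is given. The glycosyltransferase gene UGT75C1 was 64.1-fold higher. The camera adjusted p was 5.0e-08, and the adjusted p = 0.414 with an estimated correlation. In the starch and sugar list 13 of 22 genes rose and 1 fell (the same adjusted over the list alone; adjusted p = 1.6e-04, and adjusted p = 0.339 with an estimated correlation). The debranching enzyme gene ISA3 rose 26.9-fold and the beta-amylase gene BAM3 9.49-fold, while the sucrose synthase gene SUS4 was 7.20-fold lower. Of 22 cytosolic ribosomal protein genes 4 rose, among them RPL24A by 2.59-fold, and none fell (4 adjusted over the list alone; adjusted p = 8.1e-05, and adjusted p = 0.481 with an estimated correlation).

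Photosynthesis genes fell, 16 of 25 and with none higher, also when adjusted over the list alone. RBCS2B, for the small subunit of Rubisco, was 12.8-fold lower (-3.67 ± 0.12) and the antenna gene LHCB4.2 8.42-fold lower. The camera adjusted p was 2.6e-06, with adjusted p = 0.414 with an estimated correlation, and probes of the RBCS and LHCB2 genes can carry signal from near-identical copies. Auxin response genes fell as well, 14 of 22 with none higher (the same adjusted over the list alone; adjusted p = 2.6e-06, and adjusted p = 0.146 with an estimated correlation). IAA6 was 34.7-fold lower and PIF4, a growth-promoting regulator, 16.9-fold lower. Heat shock genes fell in 14 of 23 cases with none higher (the same adjusted over the list alone; adjusted p = 7.9e-04, and adjusted p = 0.146 with an estimated correlation), among them MBF1C by 14.4-fold and HSP90.1 by 11.9-fold. Of the 16 genes of the dark and sugar starvation list, 12 fell and 1 rose (the same adjusted over the list alone; adjusted p = 0.0026, and adjusted p = 0.414 with an estimated correlation). SEN1 was 53.7-fold and DIN10 23.4-fold lower, and TPS5 was 3.43-fold higher.

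Smaller falls occurred in the jasmonate list (10 of 20 lower, among them VSP2 by 17.2-fold; adjusted p = 0.029, and adjusted p = 0.722 with an estimated correlation) and the gibberellin list. In the latter 7 of 18 were lower and GA3OX2, for a synthesis enzyme, was 3.25-fold higher (8 lower adjusted over the list alone; adjusted p = 0.020, and adjusted p = 0.146 with an estimated correlation). With normexp the gibberellin list's mean shrank from -0.81 to -0.13 and no longer passed. In the cell wall loosening list 7 of 21 fell, with the expansin gene EXPA8 28.2-fold lower and EXPA10 2.77-fold higher (adjusted p = 0.049, and adjusted p = 0.414 with an estimated correlation). That list's test no longer passed when untreated replicate 3, cold replicate 1 or cold replicate 3 was left out, with the replicate number as a block under either numbering of the arrays at 4 h, or with only the 6 arrays compared. The circadian clock list moved both ways, with 10 of 25 higher and 5 lower (adjusted p = 0.119). PRR5 was 14.8-fold and RVE2 12.2-fold higher, LNK2 was 5.15-fold lower, and TOC1 was 5.53-fold higher. CCA1 and LHY differed by 0.70 ± 0.11 and 0.00 ± 0.22 on the log2 scale and were not called.

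For each list above and below whose count adjusted over the list alone is not given, it equalled the count given. The other lists did not pass camera in cold. Abscisic acid and dehydration genes gave 6 higher and 2 lower of 26 (adjusted p = 0.694), with RD29B 5.72-fold higher and HAI1 3.13-fold lower. The proline list gave 1 higher of 8 (0.544), and PRODH1, for proline breakdown, differed by -0.53 ± 0.22 and was not called. Salicylate defence gave 3 higher and 1 lower of 9 (0.678), with PR5 22.5-fold higher. The cell cycle list had 2 lower of 29 (0.134), light stress and reactive oxygen 2 higher and 3 lower of 11 (0.828), touch and wounding 3 and 3 of 15 (0.828), and lipid desaturation 1 and 1 of 10 (0.753). Flowering time gave 4 higher and 1 lower of 16 (0.604): VIN3, which responds to long cold, was at least 46.1-fold higher, and the floral repressor gene FLC differed by -0.40 ± 0.21 and was not called. Root markers gave 1 higher and 5 lower of 12 (0.340), with the nitrate transporter gene NRT2.1 30.5-fold higher and PYK10 6.29-fold lower. None of 11 reference genes was called by limma (0.374), and the median log2 difference of the list was 0.27. Of these genes, 8 had an adjusted p under 0.05 and missed only the 2-fold threshold.

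The direction balance of the cold comparison depended on scaling. The median of all genes shifted by 0.21 with normexp background correction and 0.18 with median scaling, and 2586 higher and 1583 lower, or 3442 higher and 2477 lower, genes were then called. With scan day as a block the counts were 2643 and 3034. Both groups were spread alike over the scan days, so this block could not alter the fold changes. Of 5547 genes called without scan day 1, 99.7% lay on the called side on the arrays of that day. Every untreated array lay alone on its slide, so slide could not enter this comparison as a block. The arrays at 24 h lay on the slides of the cold arrays, and 943 genes differed between them and untreated, against 5666 in cold.

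**Figure D2:**
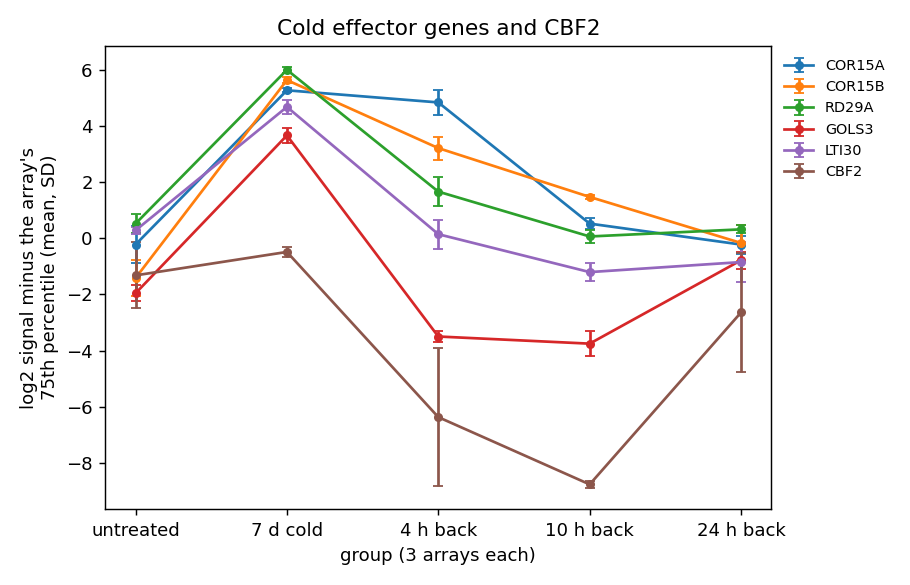
Points give the mean log2 signal relative to the array's 75th percentile (vertical axis) of 6 genes in the 5 groups (horizontal axis), with bars for the SD of 3 arrays. COR15A stood at 5.26 in cold, 4.83 at 4 h and 0.52 at 10 h.

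At 4 h after the return, 3734 genes differed from cold, 1963 higher and 1771 lower. This comparison and those at 10 and 24 h address deacclimation. The daily light period, the age and the hour of the day at sampling may differ between the groups too. GOLS3 fell most, 142-fold with a log2 fold change of -7.15 ± 0.23 (n = 3 arrays per group; adjusted p = 1.1e-09). UGT78D3, for a flavonol glycosyltransferase, BBX29, CBF3 and XTH33 were 43.7-fold, 39.4-fold, 29.3-fold and 24.8-fold lower. BBX17, a B-box regulator gene, rose most, 82.3-fold (6.36 ± 0.43), ahead of JAL23 (36.8-fold), the iron-related regulator gene BHLH100 (27.9-fold), GASA6 (26.9-fold) and PGL5 (24.99-fold). Of 20 cold effector genes 13 fell and none rose (the same adjusted over the list alone; adjusted p = 1.9e-06, and adjusted p = 0.235 with an estimated correlation). RD29A was 20.1-fold lower, whereas COR15A differed by -0.43 ± 0.29 and was not called. Of 21 cold transcription factors 11 fell (11 lower and 1 higher adjusted over the list alone; adjusted p = 7.8e-04, and adjusted p = 0.556 with an estimated correlation), with CBF2 58.7-fold lower (-5.87 ± 1.13; above background on 2 of the 3 arrays at 4 h) and CBF1 at -2.29 ± 1.29, not called.

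Clock genes fell at 4 h in 11 of 25 cases and rose in 2 (the same adjusted over the list alone; adjusted p = 7.4e-04, and adjusted p = 0.235 with an estimated correlation). CCA1 was 24.1-fold and LHY 15.9-fold lower, RVE1 was 21.6-fold lower, and PRR3 was 4.86-fold higher. Heat shock genes rose in 13 of 23 cases (the same adjusted over the list alone; adjusted p = 0.0020, and adjusted p = 0.235 with an estimated correlation), with MBF1C 17.7-fold and HSFA2 12.0-fold higher. With normexp the list's mean rise of 0.44 no longer passed. Photosynthesis genes rose in 11 of 25 cases (the same adjusted over the list alone; adjusted p = 6.2e-05, and adjusted p = 0.75 with an estimated correlation), with RBCS2B 10.3-fold higher. The flavonoid list, with 4 lower and 1 higher of 22, did not pass (adjusted p = 0.051), nor did starch and sugar (8 lower and 1 higher) or jasmonate (8 higher, VSP2 by 10.0-fold). All 3 passed with slide or scan day as a block, with mean log2 changes of -0.99 and -1.07, -0.82 and -0.81, and 0.97 and 1.04. Either block leaves only replicates 1 and 3 at 4 h in this comparison. The flavonoid and jasmonate lists also passed with the replicate number. None of the 3 passed with an estimated correlation, at 0.75 without a block and 0.678 and 0.625 with slide or scan day, and with the replicate number these lists stood at 0.785 and 0.780. PAP1, for an anthocyanin regulator, was 2.62-fold higher, a call that ended with slide or scan day as a block and with array weights (0.96, 0.99 and 0.84). Cell cycle genes had 2 of 29 higher (adjusted p = 0.0034, and adjusted p = 0.75 with an estimated correlation). Ribosomal protein genes were lower by a mean of -0.39 with no call (adjusted p = 0.0098, and adjusted p = 0.75 with an estimated correlation), which no longer passed with normexp or without replicate 1 at 4 h.

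With slide as a block among the 12 arrays of cold and deacclimation, 2019 genes were higher and 1890 lower at 4 h than in cold, and with scan day as a block 2071 and 1982. Both blocks take replicate 2 at 4 h out of the comparison. Of genes called without slide 2 or without slide 6, 99.2% and 98.3% lay on the called side on that slide. Normexp called 923 higher and 1830 lower genes, and it shifted the median of all genes by -0.19 at 4 h, -0.19 at 10 h and -0.20 at 24 h. Median scaling called 1697 higher and 2110 lower genes at 4 h. It shifted the median of all genes by -0.082 at 4 h, -0.14 at 10 h and -0.099 at 24 h.

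At 10 h after the return, 2684 genes were higher and 2233 lower than in cold. ELIP2 fell most, 172-fold (-7.43 ± 0.63; n = 3 arrays per group; adjusted p = 6.7e-07), with GOLS3, ELIP1, CCA1 and LEA4-5, for a late embryogenesis abundant protein, 170-fold, 78.4-fold, 77.9-fold and 75.9-fold lower. JAL23 and GASA6 were 98.8-fold and 98.7-fold higher, and BBX17, BHLH100 and PGL5 were 85.6-fold, 68.4-fold and 67.5-fold higher. COR15A was now 26.8-fold lower than in cold (-4.74 ± 0.29), and 15 of 20 cold effector genes had fallen with none higher (the same adjusted over the list alone; adjusted p = 7.0e-08, and adjusted p = 0.221 with an estimated correlation). CBF2 was at least 134-fold lower. Flavonoid genes fell in 17 of 22 cases (the same adjusted over the list alone; adjusted p = 5.4e-04, and adjusted p = 0.602 with an estimated correlation), with F3H 8.17-fold and CHS, for the first enzyme of the pathway, 5.48-fold lower.

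Photosynthesis genes rose in 13 of 25 cases at 10 h (the same adjusted over the list alone; adjusted p = 9.0e-06, and adjusted p = 0.602 with an estimated correlation). Jasmonate genes rose in 10 of 20 (adjusted p = 0.023, and adjusted p = 0.627 with an estimated correlation), with VSP2, for a storage protein, 31.6-fold higher. This list's test no longer passed without replicate 1 at 10 h. Cell cycle genes rose in 9 of 29 cases (the same adjusted over the list alone; adjusted p = 0.0041, and adjusted p = 0.602 with an estimated correlation), with CYCB1;3 2.76-fold higher. Abscisic acid and dehydration genes fell in 10 of 26 (the same adjusted over the list alone; adjusted p = 0.0041, and adjusted p = 0.602 with an estimated correlation), with NCED3, for a synthesis enzyme, 6.88-fold lower. The auxin list gave 4 higher of 22 and did not pass (adjusted p = 0.302). Cold transcription factors (11 of 21 lower; adjusted p = 0.0024), clock genes (10 of 25 lower and 3 higher; 0.0056), starch and sugar (10 of 22 lower and 1 higher; 0.018) and ribosomal protein genes (2 of 22 lower; 9.1e-04) passed too, each at 0.602 with an estimated correlation, and starch and sugar not with normexp. With slide as a block, which could not alter these fold changes, 2693 and 2239 genes were called. Of genes called without slide 2, 4 or 6, 99.7%, 99.5% and 99.3% lay on the called side on that slide. Normexp called 1379 higher and 2089 lower, and median scaling 2203 and 2834.

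At 24 h after the return, 2893 genes were higher and 2638 lower than in cold. GASA6 rose most, 298-fold (8.22 ± 0.36; n = 3 arrays per group; adjusted p = 3.5e-09), and LHCB2.3, BBX27, PGL5 and JAL23 were 111-fold, 79.2-fold, 71.3-fold and 63.5-fold higher. COR27 fell most, 201-fold (-7.65 ± 0.19), with LEA4-5, ELIP2, COR15B and RD29A 62.8-fold, 57.9-fold, 55.5-fold and 51.0-fold lower, and COR15A 44.8-fold lower. Cold effector genes fell in 16 of 20 cases and RCI2B rose 3.02-fold (the same adjusted over the list alone; adjusted p = 1.0e-06, and adjusted p = 0.241 with an estimated correlation). Flavonoid genes fell in 20 of 22 (the same adjusted over the list alone; adjusted p = 2.1e-05, and adjusted p = 0.603 with an estimated correlation), with PAP2 15.1-fold and TT8 11.03-fold lower.

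Photosynthesis genes rose in 18 of 25 cases at 24 h (the same adjusted over the list alone; adjusted p = 1.3e-06, and adjusted p = 0.564 with an estimated correlation), with RBCS2B 13.8-fold higher. Auxin response genes rose in 11 of 22 with none lower (the same adjusted over the list alone; adjusted p = 1.8e-04, and adjusted p = 0.241 with an estimated correlation), with SAUR19 56.9-fold and PIF4 13.6-fold higher. EXPA8, for an expansin, was 35.3-fold higher, while its list gave 8 higher and 5 lower of 21 (adjusted p = 0.296). VIN3 was called lower, with signal above background on 1 of the 3 arrays at 24 h, so no fold is given. Starch and sugar (11 of 22 lower and 1 higher; adjusted p = 0.0033), cell cycle (9 of 29 higher; 0.0062) and ribosomal protein genes (1 of 22 lower; 9.1e-04) passed too, at 0.564, 0.603 and 0.603 with an estimated correlation. With slide as a block, which could not alter these fold changes, 2900 and 2638 genes were called. Of genes called without slide 2, 4 or 6, 99.6%, 99.1% and 98.2% lay on the called side on that slide. Normexp called 1583 higher and 2500 lower.

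By 24 h most genes changed in cold had moved in the opposite direction. Of the 2641 genes raised in cold, 2070 (78.4%) were called lower at 24 h than in cold, against 330 for independent lists. Of the 3025 lowered genes, 2302 (76.1%) were called higher, against 415. Both comparisons share the cold arrays, which can raise these overlaps. In 20 simulations of unchanged groups both overlaps held 0 genes. What the sharing adds among genes that did change was not measured. The log2 fold changes of the 2 comparisons correlated across genes at -0.907, against -0.503 simulated for unchanged groups, with a covariance of -1.21 against -0.026. Of the raised genes 1203 were already lower than in cold at 4 h, 478 first at 10 h and 505 first at 24 h, while 455 were not called lower at any time. Of the lowered genes 1479, 560 and 433 first rose at these times and 553 did not.

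Raised genes kept 38.7% ± 10.7 (SD, n = 3 arrays) of their cold change at 4 h, 23.3% ± 3.32 at 10 h and 8.80% ± 4.97 at 24 h, as medians over genes. Lowered genes kept 43.4% ± 6.09, 25.6% ± 0.683 and 10.4% ± 2.31. On the 3 arrays at 4 h raised genes kept 28.9%, 50.1% and 36.7%, and the highest value belonged to replicate 2, the array on a slide and scan day of its own. By list, the 20 cold-raised flavonoid genes kept 84.6%, 64.9% and 38.5% at the 3 times, and the 16 cold-lowered photosynthesis genes kept 27.5%, 10.5% and -3.68%. The 14 cold-lowered auxin genes kept 85.6%, 78.2% and 21.9%.

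**Figure D3:**
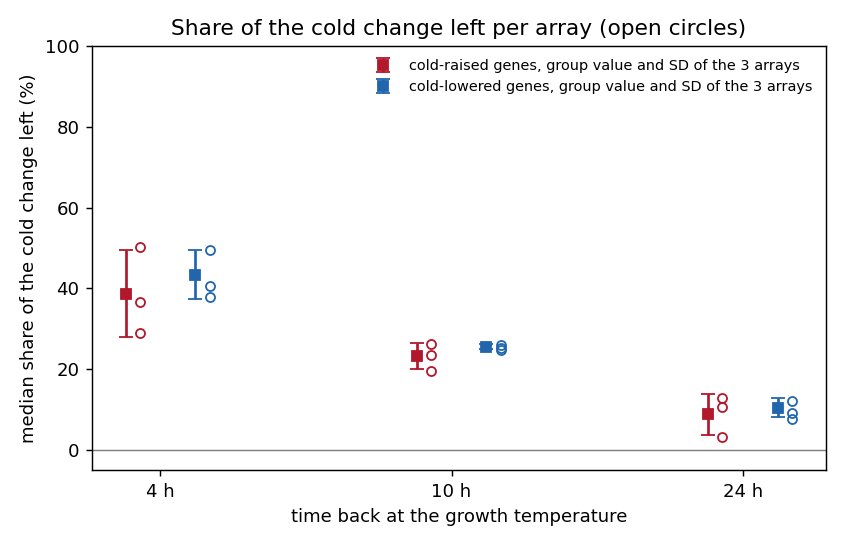
Squares give the median share of the cold change left (vertical axis, percent) at 4, 10 and 24 h (horizontal axis) for genes raised (red) or lowered (blue) in cold, with bars for the SD of 3 arrays and open circles for single arrays. The share was 38.7% and 43.4% at 4 h and 8.80% and 10.4% at 24 h. The bars leave out the spread of the untreated and cold arrays.

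**Figure D4:**
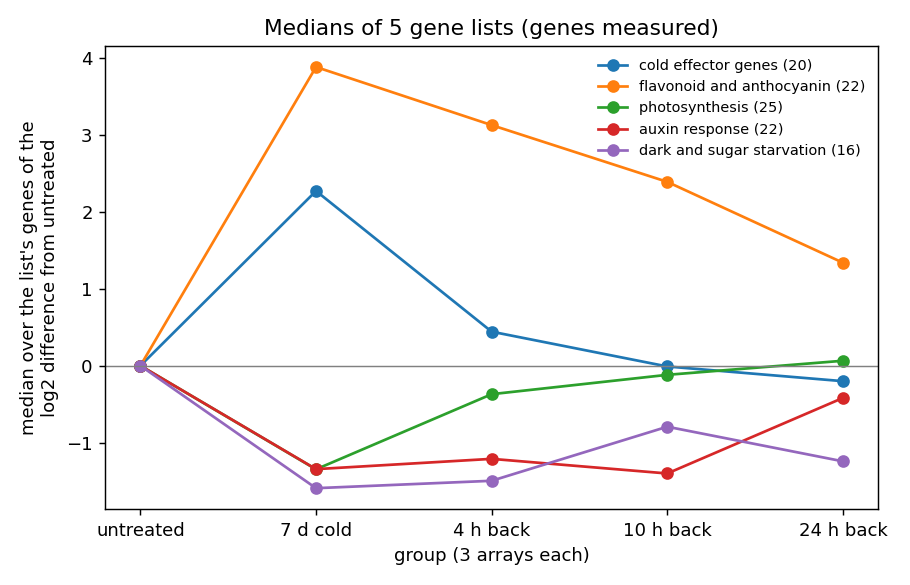
Lines join the medians, over the measured genes of 5 lists, of the log2 difference of each group mean from untreated (vertical axis) in the 5 groups (horizontal axis, 3 arrays each). The flavonoid list stood at 3.89 in cold and 1.34 at 24 h, and photosynthesis at -1.35 and 0.06.

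Compared with untreated seedlings, 943 genes differed after 24 h at the growth temperature, 287 higher and 656 lower. NRT2.1 was 25.1-fold higher (4.65 ± 0.36; n = 3 arrays per group; adjusted p = 1.3e-05), PCC1 12.7-fold and UGT79B1 11.6-fold higher. SEN1 was 13.5-fold lower. JAZ7 was 10.6-fold lower, a call lost with normexp (-2.20), and M17 22.5-fold lower (-4.49 ± 1.16), a call lost without untreated replicate 1 (-4.31) or replicate 3 at 24 h (-3.75). Flavonoid genes were higher in 12 of 22 cases with none lower (13 adjusted over the list alone; adjusted p = 7.9e-09, and adjusted p = 0.580 with an estimated correlation). Dark and sugar starvation genes were lower in 10 of 16 with none higher (the same adjusted over the list alone; adjusted p = 2.3e-07, and adjusted p = 0.330 with an estimated correlation). The auxin list was lower on average by a mean of -0.47, with 1 of 22 called (adjusted p = 7.1e-05, and adjusted p = 0.330 with an estimated correlation). Another 6 lists passed: heat shock (mean -0.70, 6 of 23 lower and 7 adjusted over the list alone; adjusted p = 0.028), jasmonate (-0.45, 3 lower; 0.029), starch and sugar (0.34, 2 higher; 0.0056), abscisic acid and dehydration (-0.29, 2 lower; 0.028), cold transcription factors (-0.49; 0.0056) and cell cycle (0.26; 6.3e-04). In the last 2 limma called 0 of 21 and 0 of 29 genes, with 8 and 15 at an unadjusted p under 0.05. An adjusted p under 0.05 was reached by 3 and 7 of them, which missed the 2-fold threshold. None of the 6 passed with an estimated correlation (0.580 to 0.708). Heat shock also failed with normexp, with probes above background on all 15 arrays, with the authors' table and without untreated replicate 3. Jasmonate failed with fry and without untreated replicate 1 or 2 or replicate 2 at 24 h, abscisic acid with fry and without untreated replicate 2 or replicate 3 at 24 h, and cold transcription factors without replicate 3 at 24 h. None of 25 photosynthesis genes was called by limma, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.685), and root markers gave 1 higher and 3 lower of 12 (0.113). Of the 2641 cold-raised genes 152 were also higher at 24 h than untreated, against 35.9 for independent lists, and of the 3025 lowered genes 324 were also lower, against 94.0. In the opposite direction, 65 of the raised genes were lower at 24 h than untreated, against 82.1, and 31 of the lowered genes were higher, against 41.1. Both comparisons share the untreated arrays, so cold and 24 h were also set against different untreated arrays, in 6 ways chosen after seeing the data, where a lone array is assumed to vary like the other groups. The overlaps were then between 3.89 and 4.49 times (higher) and between 2.76 and 3.39 times (lower) those of independent lists. An offset common to the untreated slides would enter these values too. With scan day as a block, which could not alter these fold changes, 298 and 677 genes were called. Of 613 genes called without scan day 1, 97.4% lay on the called side on that day. Normexp called 146 and 282, and slide and untreated state cannot be told apart for these genes.

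Between 4 and 10 h, 324 genes rose and 198 fell. JMJD5, for a demethylase tied to the clock, rose 11.7-fold (3.55 ± 0.13; n = 3 arrays per group; adjusted p = 3.8e-08) and COR27 6.70-fold. COR15A fell 19.8-fold (-4.31 ± 0.29), the clock gene PRR9 12.4-fold and TSPO 14.0-fold, the last a call that ended with slide as a block (-3.35). VSP1 was 5.89-fold higher, a call lost without replicate 1 or 3 at 10 h or replicate 2 or 3 at 4 h, with normexp, with no filter on dim probes, with slide or scan day as a block and with only the 6 arrays compared. Its log2 fold change then ran from 1.84 to 2.65, against 2.56. Abscisic acid and dehydration genes fell in 6 of 26 cases (7 adjusted over the list alone; adjusted p = 1.3e-06, and adjusted p = 0.413 with an estimated correlation), and flavonoid genes in 5 of 22 (7 adjusted over the list alone; adjusted p = 1.8e-05, and adjusted p = 0.767 with an estimated correlation). The counts rested on replicate 2 at 4 h: without it 197 and 106 genes were called, and with slide as a block 107 and 81. The slide block also takes that array out. Of genes called without slide 2 or without slide 6, 91.9% and 86.9% lay on the called side on that slide. Normexp called 67 and 68. Heat shock (adjusted p = 6.1e-04), cold effector (0.0011), photosynthesis (0.0019), ribosomal protein (0.0059) and cell wall loosening genes (0.015) passed camera too, with mean shifts of -0.56 (4 lower, 6 adjusted over the list alone, and 1 higher), -0.63, 0.20, -0.20 and 0.24, and not with an estimated correlation (0.413 to 0.790).

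Between 10 and 24 h, 508 genes rose and 427 fell. The morning-phased clock genes LHY and CCA1 rose 92.7-fold (6.53 ± 0.22; n = 3 arrays per group; adjusted p = 2.0e-09) and 49.0-fold, and the kinase gene CIPK20 rose 70.9-fold. COR27, JMJD5 and PRR3 fell 65.7-fold, 28.2-fold and 23.7-fold. Clock genes rose in 10 of 25 cases and fell in 10 (the same adjusted over the list alone), and the list's camera test did not pass (adjusted p = 0.113). Auxin response genes rose in 10 of 22 with none lower (the same adjusted over the list alone; adjusted p = 8.0e-12), and this call held with an estimated correlation (adjusted p = 0.017). Flavonoid (-0.74, 6 lower and 10 adjusted over the list alone; adjusted p = 0.020), cell wall loosening (0.34, 2 higher and 3; 0.015) and abscisic acid and dehydration genes (0.27, 4 higher and 1 lower, 4 and 2; 0.015) passed camera too, and not with an estimated correlation (0.559 to 0.878). With slide as a block, which could not alter these fold changes, 511 and 437 genes were called. Of genes called without slide 2, 4 or 6, 97.4%, 97.1% and 96.5% lay on the called side on that slide. Normexp called 304 and 244.

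**Figure D5:**
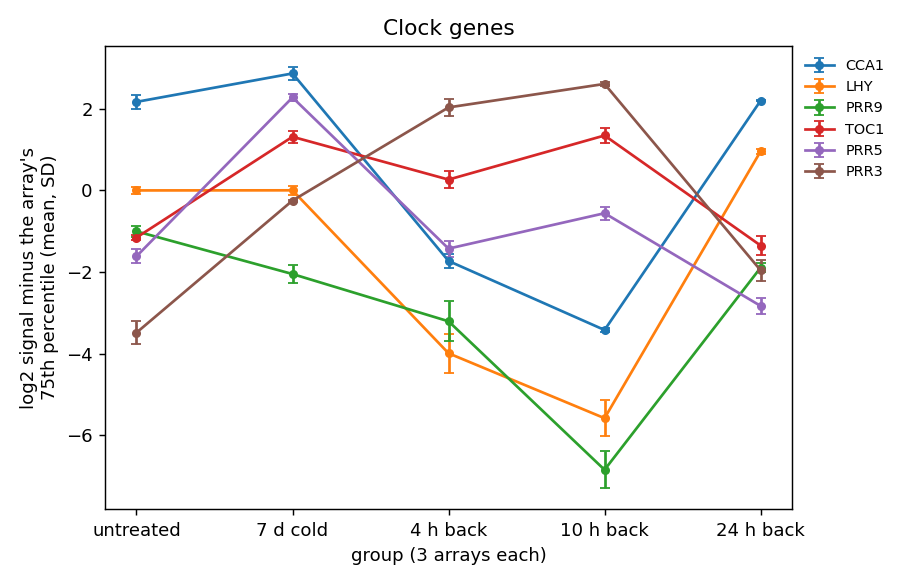
Points give the mean log2 signal relative to the array's 75th percentile (vertical axis) of 6 clock genes in the 5 groups (horizontal axis), with bars for the SD of 3 arrays. CCA1 was 77.9-fold lower at 10 h than in cold and rose 49.0-fold from 10 to 24 h.

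In the comparisons added after seeing the data, 4 h differed from untreated in 1016 higher and 1656 lower genes and 10 h in 840 and 1214. Auxin response genes were lower than untreated in 12 of 22 cases at 4 h (adjusted p = 5.5e-09) and 14 of 22 at 10 h (adjusted p = 3.4e-11). Both calls held with an estimated correlation (adjusted p = 0.0497 and adjusted p = 0.0207). Clock genes were called in both directions at 10 h, 9 higher and 12 lower than untreated of 25.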

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

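The tests of slide, sampling hour, clock phase and steady return were chosen after the related results were seen, as were the slope test of the array at 4 h and the second of its mixing tests. The first mixing test and the splits were set before their results were seen.

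The change from cold differed between groups at 4 h and 24 h: the difference itself was called for 1699 genes in limma, 995 higher and 704 lower at 24 h. It was called for 849 and 592 with slide as a block, 901 and 595 with scan day, and 1008 and 710 with the replicate number, or 996 and 703 with numbers 1 and 2 at 4 h exchanged as in the authors' value table. The slide and scan day blocks take replicate 2 at 4 h out of this comparison. In opposite directions from cold at 4 h and 24 h, 17 genes were called. The log2 difference between 24 h and 4 h was -3.99 for PRR3, -2.81 for PAP1 and 4.48 for CIPK20. A signal also appeared in data no comparison used: 874 of the 2662 tested probes without a locus (32.8%) were called in cold, 469 higher and 405 lower.

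A first pattern is the 943 genes that differed from untreated at 24 h. A sampling hour far enough from that of untreated to move clock genes is argued against by their median absolute log2 difference of 0.26, at most 0.43 on any array, against 2.23 at 10 h. For an offset of the slides that held the untreated arrays, the test was whether these genes lay on the same side in cold relative to 24 h as in 24 h relative to untreated. It decides nothing: 42.2% of the higher and 39.9% of the lower genes did, but so did 46.3% of genes not called, because the arrays at 24 h enter both differences. The slides and the untreated state therefore cannot be told apart for this set. Incomplete return, overshoot, the shorter daily light period during the cold and a difference in age stay open beside them.

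A second pattern is the clock genes, which stood away from untreated at 10 h and near it at 24 h. A steady return from the cold level is argued against: 11 of 25 clock genes (44.0%, against 3.04% of all genes) lay over 1 log2 unit and 2 standard errors outside the range between cold and untreated at 10 h. The hour of the day at sampling is a candidate explanation: of 17 genes listed by textbook phase, 17 lay below untreated if morning-phased and above it if evening-phased at 10 h, as did 17 at 4 h, 14 in cold and 8 at 24 h, so this placement is not particular to 10 h. A response of the clock to warming itself cannot be told apart from this, because 0 untreated arrays are known to come from the hours of the deacclimated ones. CBF1, CBF2 and COR27, which follow the clock as well, share this doubt. The doubt is not limited to these genes. The median absolute log2 difference of the clock genes from untreated was 1.59 at 4 h and 2.23 at 10 h. The hour of the day therefore cannot be told apart from deacclimation in the gene counts, lists and shares left at these times.

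The last pattern is replicate 2 at 4 h, which lay nearer the cold arrays. Across 6443 genes, its deviation from the other arrays at 4 h had a slope of 0.149 on the difference between cold and 10 h. This was 1.57 times the largest absolute slope of the other 8 deacclimated arrays. The bound of 2 set for it could not be passed. Each array was set against the others of its group, so the slopes at 4 h (0.149, -0.095 and -0.054) cancel out. The slope test therefore decides nothing. Slopes ran from -0.020 to 0.012 at 10 h, on the difference between cold and 24 h, and from -0.029 to 0.037 at 24 h. Slide or scan day and an earlier point of the return cannot be told apart, since the array was alone on its slide and scan day. For cold RNA mixed into the sample, 53.1% of 32 genes that fell over 16-fold allowed less than 5% of it. By the rule set before the result was seen, over 50% counts against mixing. The genes that rose would need a median of 23.7%, which 15.6% of the 32 genes allow. A mixed-in share would be the same for every gene, and the 32 genes allowed a median of 3.11%, with a lower quartile of 0.42%. For these genes, the values argue against mixing of the size that the genes that rose would need. The lower quartile of the genes that rose was 2.22%, so a smaller share may remain a partial source and stays open.

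For each comparison of 6 arrays, 1 of the 10 splits into 3 and 3 gave as many genes, the real one, and so few splits cannot give a share under 0.05. The real count and the highest of the other splits were 5666 and 0 for cold against untreated, 3734 and 9, 4917 and 0, and 5531 and 0 for 4, 10 and 24 h against cold, and 943 and 1 for 24 h against untreated. They were 522 and 0 for 10 h against 4 h, 935 and 0 for 24 h against 10 h, 2672 and 1 for 4 h against untreated, 2054 and 0 for 10 h against untreated, and 1699 and 0 for 24 h against 4 h. For genes called in cold and in the opposite direction at 24 h, 1 of 100 splits of the 9 arrays, the real one, gave as many (4372, against 342 at most in the others). These splits take all 9 arrays as interchangeable, and cold arrays unlike the rest are enough to give this outcome. They therefore do not decide whether the reversal itself could arise by chance.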

How the results depend on the processing

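The block by scan day, and every alternative for 4 h and 10 h against untreated and 24 h against 4 h, were chosen after seeing the data, and the other alternatives named here before. Leaving the fold threshold out or testing against it changes every count by construction. Without it the counts, higher and lower, were 7371 and 7342 in cold, 6591 and 6421, 7158 and 7017, and 7323 and 7430 at 4, 10 and 24 h against cold, 2373 and 2190 at 24 h against untreated, 1539 and 1131 from 4 to 10 h, 2079 and 2009 from 10 to 24 h, 5442 and 5004, and 4441 and 3956 at 4 and 10 h against untreated, and 3889 and 3755 at 24 h against 4 h. Then 6276 cold-raised genes fell and 6164 cold-lowered genes rose by 24 h, and lowered genes kept 34.1%, 19.6% and 5.89% of their change at 4, 10 and 24 h. The treat test against a log2 fold change of 1 gave, in that order, 1228 and 1677, 698 and 546, 1239 and 844, 1550 and 1192, 24 and 49, 3 and 7, 116 and 79, 263 and 543, 243 and 300, and 217 and 137, with 853 and 1219 genes moving back and raised genes keeping 27.3% at 10 h.

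With normexp background correction, 1583 genes were lower in cold and 923, 1379 and 1583 higher at 4, 10 and 24 h than in cold. It gave 146 and 282 genes at 24 h against untreated, 67 and 68 from 4 to 10 h, 304 and 244 from 10 to 24 h, 649 and 998, and 544 and 717 at 4 and 10 h against untreated, 533 and 373 at 24 h against 4 h, 1165 cold-lowered genes that rose by 24 h, and 19.8% (raised) and 28.7% (lowered) of the cold change left at 10 h. It also reversed log2 fold changes: ERF6 0.66, HSP21 0.36 and JAZ8 0.035 in cold, JAZ7 -0.21 and APX2 -0.45 at 4 h, HSP21 -0.69 at 10 h and GA2OX7 -0.63 at 24 h against cold. The cause was not tested. The share lowered genes kept at 10 h was 27.5% with median scaling (7.53% at 24 h), 26.7% with no filter on dim probes, 24.7% with probes above background on all 15 arrays and 26.8% from the authors' value table. From 4 to 10 h, 107 genes rose and 81 fell with slide as a block, 188 and 108 with scan day as a block, and 213 and 130 with only the 6 arrays compared. The slide and scan day blocks take out replicate 2 at 4 h, and without that array 197 and 106 genes were called. What else lowered these counts was not tested. With the replicate block, which could not alter fold changes, no count moved by over 1.5 times (303 and 662 genes at 24 h against untreated). The cell wall list in cold lost its call with it.

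Leaving out 1 array at a time, genes higher from 4 to 10 h ran from 197 to 375 and lower genes from 106 to 259, lowest without replicate 2 at 4 h in both cases, and the share lowered genes kept at 10 h from 23.8% to 26.47%. All other counts stayed within 1.5 times their value in the leave-outs, and their ranges included 2509 to 2776 and 2946 to 3121 for cold and 245 to 305 and 509 to 763 for 24 h against untreated. Of 290 named gene results that were called, 51 lost the call in some alternative and 21 when an array was left out. An estimated correlation ended 44 of 44 list calls in the planned comparisons with cold, and of 24 h with untreated, that were tracked through the alternatives. Fry ended 2 of these calls and passed 45 list results that camera did not, but it does not compare a list with other genes. Signal over background limits dim genes: 61.7% to 66.9% of spots per array were well above it.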

Other observations

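The comparisons with random lists below were chosen after seeing the data; 27 pairs of a list and a time were compared. The 12 cold-lowered genes of the dark and sugar starvation list, such as SEN1 and DIN10, kept 64.7% at 24 h, against 10.4% over all cold-lowered genes, and 63.7%, 63.7% and 66.7% on the 3 arrays. The 10 cold-lowered jasmonate genes kept 57.1% at 24 h, with 36.1%, 72.0% and 42.8% on the 3 arrays and a random range of -7.77% to 31.5%. At 4 and 10 h these genes kept 34.2% and 34.4%, inside the ranges of 16.5% to 70.3% and 2.59% to 51.2%. The 14 cold-lowered heat shock genes kept 11.8% at 4 h, below the range of 20.9% to 67.8% that held 95% of random lists, and 45.6% at 10 h, inside its range of 6.41% to 49.9%. The photosynthesis shares lay inside their ranges at 4, 10 and 24 h, at percentiles 12.7, 6.78 and 5.62. The cold effector genes raised in cold kept 26.9%, 12.1% and -3.44% at 4, 10 and 24 h. Their random ranges were 26.8% to 64.8%, 13.4% to 50.6% and 2.56% to 22.2%. The share thus lay just inside the range at 4 h and below it at 10 and 24 h.

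A hypothesis is that flavonoid genes may return later than other cold-raised genes. It was prompted by the 20 raised members keeping 38.5% at 24 h (39.7%, 41.8% and 35.3% on the 3 arrays), where random lists of cold-raised genes matched on the size of the rise ranged from 4.83% to 23.2%. At 4 and 10 h, the times that did not prompt it, the list kept 84.6% (73.3%, 104% and 70.9% on the 3 arrays) and 64.9%, at percentiles 99.96 and 99.89 of 10000 random lists. The highest share at 4 h came from replicate 2, alone on its slide and scan day. Without it the list kept 72.1%, at percentile 99.6. Likewise auxin genes may return later than other cold-lowered genes, as their 14 lowered members kept 78.2% at 10 h (77.3%, 78.1% and 74.7% on the 3 arrays; random lists 8.53% to 48.8%). Of the other times, the share at 4 h (85.6%) lay at percentile 99.96 and that at 24 h (21.9%) at percentile 84.6, inside the range, so this one stays undecided. The 10 cold-raised clock genes kept 103% at 10 h, also at percentile 100 and between 92.5% and 106% on the 3 arrays. The hour of sampling, a candidate explanation for the clock genes, therefore stays open for the auxin and flavonoid shares as well. Neither share was tested against it. The times share the cold and untreated arrays and are no independent samples. Random lists take genes as independent, and listed genes vary together, so these percentiles overstate the certainty. The untreated arrays lay on slides of their own.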
